A study of Caenorhabditis elegans with 16 samples.

How the data were processed

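Polyadenylated RNA of whole C. elegans was sequenced in paired reads of 150 bases from 1 µg of total RNA per sample, per the labels' protocols. These name 2 library kits, TruSeq and KAPA HyperPrep, without saying which sample had which. Parents grew for 5 days on the first food, filtered L1 larvae were placed on the second, and animals were harvested on day 3. The submitters' processing notes name FastQC 0.11.6, Trimmomatic 0.38, HISAT2 2.1.0, SAMtools 1.3.1, StringTie 1.3.4 and DESeq2 1.30.1, with no role or order, and the genome build WBcel235. The values are estimated counts per gene as deposited, already whole numbers and not normalized, as judged from the values. How the estimates were turned into counts, and whether strand was used, is not given in the sources used here. Reads that fit several similar genes can be split between them in such estimates, so families of near-identical genes are uncertain.

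The deposited table held 46904 rows, of which 23752 were 0 in every library, and 46817 had an identifier in the Ensembl annotation of the same build, which gave the coordinates. Library totals of 6876419 to 14849822 counts put 3 counts in a library between 0.202 and 0.436 CPM. Floors and counting intervals (95%) cover counting error only. Groups came from the labels. In R 4.3.3, edgeR 4.0.16 was run with its default filter on low counts, which left 13868 genes, TMM factors and the robust quasi-likelihood test over all 16 libraries with a mean per group, and Benjamini-Hochberg adjustment. A gene counted as changed at an adjusted p below 0.05. Gene lists, 49 in number, were fixed before the data were examined, as were the comparisons, the rule for naming genes and most alternatives. Of them 47 had at least 4 tested members and were tested with camera in limma 3.58.1, with a preset correlation of 0.01, against the other genes.

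Named genes were bir-2 and, per pairwise comparison, the 10 highest and 10 lowest log2 fold changes among genes with a symbol, an adjusted p below 0.05, a group mean of at least 5 CPM and no overlap between the 4 values of each group, with at most 3 per family and direction. For the interaction they were 5 per direction, and for each list described up to 4 members with the smallest adjusted p. Of all tested genes 65.0% had no overlap in the group labelled wild type on E. faecalis against OP50, where chance gives 2.86%. The procedure was tested on simulated counts of 13868 genes. In the order E. faecalis in the arm labelled wild type, knockdown against OP50, E. faecalis after the knockdown food and knockdown on E. faecalis, it recovered 76, 80, 84 and 74% of genes changed 2-fold and 86, 91, 93 and 88% of genes changed 4-fold. Unchanged genes made up 3.93, 2.63, 4.59 and 3.91% of calls, and a shifted list was called in each, with 0 of 40 unshifted lists. In the simulation only a small share of genes was changed, and those changed 2-fold or 4-fold went up and down in equal number. In the data most tested genes were called in every comparison, so these rates need not hold there. Principal component 1 held 57.1% of the variance and component 2 14.3%. On the first, the OP50 control and the libraries labelled knockdown plus E. faecalis lay apart from the remaining groups.

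Alternatives were DESeq2 1.42.0, limma-voom with and without sample quality weights, other scaling factors, other filters on low counts, leaving out highly expressed gene families, only the groups compared, the replicate number as a block, each library left out in turn, stricter thresholds, other set tests, and, chosen after seeing the data, leaving out ribosomal RNA rows, thinning to the smallest total and leaving out the library farthest from its group mean. Replicates of a group differed by more than sampling noise (a chi-square per gene of at least 2.92), with Spearman correlations of 0.981 or more between them. The design did not include a group on empty-vector RNAi food, as far as the labels say, and the parents' food differed between the groups on E. faecalis.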

Results

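Polyadenylated RNA from whole Caenorhabditis elegans nematodes of the N2 laboratory strain was profiled in 16 libraries, in 4 groups of 4. Each sample held 990 animals, labelled as L4 larvae. The control group and its parents were fed OP50, the standard Escherichia coli food. The bir-2 RNAi group and its parents were fed bacteria for RNA interference against bir-2, which encodes a protein with baculoviral inhibitor-of-apoptosis repeats. Another group had parents on the bir-2 RNAi food and was itself placed on Enterococcus faecalis, a Gram-positive pathogen. The last group, labelled wild type on E. faecalis, and its parents were fed E. faecalis. Library totals ranged from 6876419 to 14849822 estimated counts, and 13868 genes were tested. Rows for ribosomal RNA held 7.19% ± 4.30 of the counts in the OP50 control, 3.82% ± 2.35 in the bir-2 RNAi group, 7.47% ± 5.73 in the libraries labelled knockdown plus E. faecalis and 0.753% ± 0.328 in the group labelled wild type on E. faecalis (SD, n = 4 each). Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which can be technical.

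The first question was whether the RNAi target was lower where the labels say so. bir-2 (WBGene00000250) lies on chromosome V, 13568850 to 13570030, plus strand, in WBcel235. Its level was 35.3 ± 4.11 CPM (counts scaled to a common library total with TMM factors) in the OP50 control and 20.3 ± 0.614 in the bir-2 RNAi group (SD, n = 4 each). It was 39.5 ± 3.71 CPM in the libraries labelled knockdown plus E. faecalis and 18.3 ± 1.98 CPM in the group labelled wild type on E. faecalis (SD, n = 4 each). Against the OP50 control the log2 fold change was -0.79 ± 0.10 in the bir-2 RNAi group (SE, edgeR adjusted p = 2.92e-07) and -0.94 ± 0.11 in the group labelled wild type on E. faecalis (edgeR adjusted p = 3.45e-08). The libraries labelled knockdown plus E. faecalis went against their label: bir-2 was higher there than in the group labelled wild type on E. faecalis, by 1.11 ± 0.11 on the log2 scale (edgeR adjusted p = 5.41e-09), and higher than in the bir-2 RNAi group by 0.96 ± 0.10 (edgeR adjusted p = 1.51e-08). In each of these 4 comparisons the 4 values of a group did not overlap the other 4, and the two-sided exact permutation p was 0.0286, the smallest that 4 against 4 can give. No empty-vector RNAi food is named in the labels, so the effect of the RNAi food as such was not separated from that of bir-2.

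**Figure D1:**
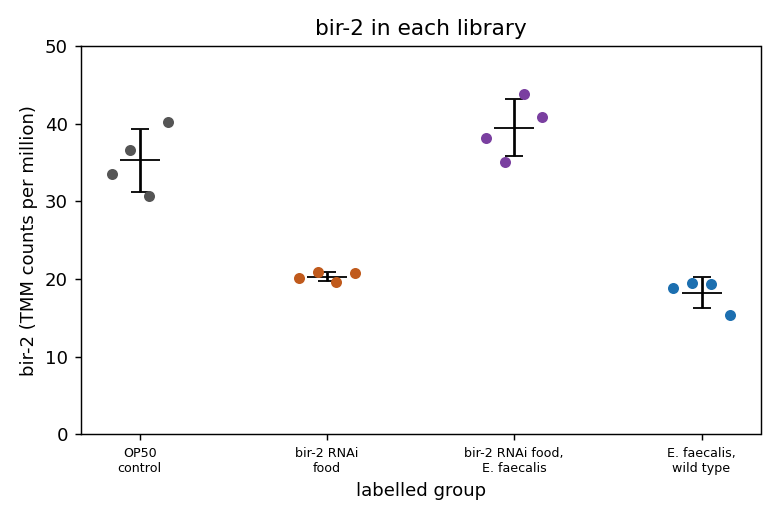
bir-2 in TMM-scaled CPM (vertical axis) in each library (points) of the 4 labelled groups, with the mean and SD of 4 libraries as bars. The libraries of the bir-2 RNAi group lie between 19.6 and 20.9, and those labelled knockdown plus E. faecalis between 35.1 and 43.8, against 30.7 to 40.3 in the OP50 control.

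The bir-2 RNAi group was set against the OP50 control to ask what the knockdown food changed without a pathogen. Lists of moulting cycle genes, cuticle collagens and neuron markers were shifted higher, and lists of cell division and oocyte genes lower, by limma's camera. With an estimated correlation the moulting and neuron calls held, and the collagen, cell cycle and oogenesis calls did not (adjusted p = 0.504, 0.191 and 0.290). noah-1, which encodes an extracellular matrix protein of the cuticle, rose by 4.61 ± 0.11 on the log2 scale (SE), to 391 ± 36.3 CPM (SD, n = 4). The collagen gene col-41 (chromosome X, 15175032 to 15176481) rose from 2.99 ± 0.242 to 218 ± 35.1 CPM, and the lipase-family gene lips-6 (chromosome IV, 12014130 to 12015686) from 0.333 ± 0.393 to 76.2 ± 10.3 CPM. The collagen gene col-95 had a log2 fold change of -3.22 ± 0.11 (SE), and fat-7, a stearoyl-CoA desaturase gene, fell from 274 ± 10.5 to 71.5 ± 4.89 CPM. In the moulting cycle list, of 24 tested members 23 rose, 1 fell and 0 did not pass (23 and 1 adjusted over the list alone), with a median log2 fold change of 3.29 (limma's camera adjusted p = 2.57e-09, and adjusted p = 0.0476 with an estimated correlation). Among the neuron markers, of 26 tested members 25 rose, 0 fell and 1 did not pass (25 and 0 adjusted over the list alone), with a median of 1.99 (limma's camera adjusted p = 2.57e-09, and adjusted p = 0.0300 with an estimated correlation). egl-3, a proprotein convertase gene of neuropeptide processing, had a log2 fold change of 2.39 ± 0.09 and ida-1 of 2.58 ± 0.10 (SE). For the nuclear hormone receptors, of 169 tested members 103 rose, 7 fell and 59 did not pass (100 and 7 adjusted over the list alone), with a median of 0.81 (limma's camera adjusted p = 3.77e-05, and adjusted p = 0.0300 with an estimated correlation). nhr-25, a receptor gene active in moulting, rose by 3.60 on the log2 scale.

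In the list of cell cycle and DNA replication genes, of 35 tested members 0 rose, 35 fell and 0 did not pass (0 and 35 adjusted over the list alone), with a median of -0.80 (limma's camera adjusted p = 2.29e-12, and adjusted p = 0.191 with an estimated correlation). cdk-1, the mitotic kinase gene, was at 209.6 ± 10.8 CPM in the OP50 control and 105 ± 7.82 CPM in the bir-2 RNAi group (SD, n = 4 each). The oogenesis and eggshell list moved alike: of 32 tested members 0 rose, 31 fell and 1 did not pass (0 and 31 adjusted over the list alone), median -0.78 (limma's camera adjusted p = 8.56e-11, and adjusted p = 0.290 with an estimated correlation). pos-1, an RNA-binding protein gene of oocytes and embryos, had a log2 fold change of -1.15 ± 0.08 (SE). Among muscle markers, of 27 tested members 25 rose, 0 fell and 2 did not pass (25 and 0 adjusted over the list alone), median 0.90 (limma's camera adjusted p = 2.69e-07, and adjusted p = 0.251 with an estimated correlation), and among cuticle collagens, of 141 tested members 99 rose, 22 fell and 20 did not pass (99 and 22 adjusted over the list alone), median 1.66 (limma's camera adjusted p = 2.99e-10, and adjusted p = 0.504 with an estimated correlation). In the programmed cell death list, which holds the pathway that gave the protein family its name, of 27 tested members 4 rose, 17 fell and 6 did not pass (5 and 17 adjusted over the list alone), median -0.52 (limma's camera adjusted p = 0.00983, and adjusted p = 0.166 with an estimated correlation). ced-9, an inhibitor of apoptosis, had a log2 fold change of -0.89 ± 0.09 and cep-1, the p53 homologue, of -1.06 ± 0.09 (SE). Genes of the dsRNA response and RNA interference were lower: of 34 tested members 2 rose, 26 fell and 6 did not pass (2 and 27 adjusted over the list alone), median -0.57 (limma's camera adjusted p = 1.36e-05, and adjusted p = 0.290 with an estimated correlation). A fall was also seen in the group labelled wild type on E. faecalis, without RNAi food as labelled. Were the labels on E. faecalis exchanged, that group's parents would have eaten RNAi food, so a fall apart from that food is not shown in this group. Against OP50, 3 of the 34 rose there, 25 fell and 6 did not pass (3 and 25 adjusted over the list alone), median -0.64 (limma's camera adjusted p = 4.29e-06, and adjusted p = 0.277 with an estimated correlation). For antimicrobial peptides in the bir-2 RNAi group, of 36 tested members 25 rose, 1 fell and 10 did not pass (25 and 1 adjusted over the list alone), median 0.94 (limma's camera adjusted p = 0.00900, and adjusted p = 0.504 with an estimated correlation), with nlp-30 at 2.23 ± 0.15 (SE).

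Further genes with large fold changes included mltn-5, which had no count in the OP50 control and was at least 189-fold higher in the bir-2 RNAi group, taking 3 counts over the group as the floor. Its reads cannot be told apart from those of hot-3, which overlaps it on the other strand, since the counting is not stated to use strand; the same holds for fat-5 and twk-42, and for hrg-7 and C15C8.7. The collagen gene col-54 rose by 5.95 ± 0.23 and the O-acyltransferase-family gene oac-1 was 168 times as high, with a counting interval of 57.1 to 816. Lower genes included ugt-63 (-3.15 ± 0.17), ugt-44 (-2.16 ± 0.14), clec-4 (-2.76 ± 0.17), hrg-7 (-2.46 ± 0.08), cyp-35A2 (-2.43 ± 0.21), gba-4 (-2.07 ± 0.10) and fat-5 (-2.97 ± 0.28), each a log2 fold change with its SE. In all, 10120 of 13868 genes changed (edgeR, adjusted p below 0.05): 5581 rose and 4539 fell, of which 3303 rose and 774 fell by at least 1 on the log2 scale. Among the called genes 55.1% rose with TMM scaling and 65.7% with upper-quartile scaling, and the median log2 fold change of all tested genes was 0.19 and 0.39 respectively.

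The group labelled wild type on E. faecalis was set against the OP50 control to ask what the pathogen changed in animals without RNAi food, as labelled. bir-2 was at a low level there (18.3 CPM, against 20.3 CPM in the bir-2 RNAi group and 35.3 CPM in the control), so every direction here is between libraries as labelled. Lists of sperm, collagen, muscle and moulting genes were shifted higher, and lists of cell division and oocyte genes lower, by limma's camera. With an estimated correlation none of these calls held (adjusted p = 0.201 to 0.291). The major sperm protein gene msp-142 rose from 39.3 ± 2.54 to 111 ± 10.5 CPM (SD, n = 4 each); its near-identical copies make the share of each copy uncertain. Among major sperm proteins, of 34 tested members 33 rose, 0 fell and 1 did not pass (33 and 0 adjusted over the list alone), median 1.47 (limma's camera adjusted p = 1.18e-13, and adjusted p = 0.291 with an estimated correlation). In the spermatogenesis list, of 51 tested members 44 rose, 5 fell and 2 did not pass (44 and 5 adjusted over the list alone), median 1.44 (limma's camera adjusted p = 3.39e-07, and adjusted p = 0.277 with an estimated correlation), with the phosphatase gene gsp-3 at 2.26 ± 0.12 (SE). Among cuticle collagens, of 141 tested members 117 rose, 8 fell and 16 did not pass (117 and 8 adjusted over the list alone), median 1.84 (limma's camera adjusted p = 1.05e-18, and adjusted p = 0.291 with an estimated correlation). col-41 was at 98.5 ± 8.98 CPM and col-62 at 353 ± 20.5 CPM, against 2.99 ± 0.242 and 59.6 ± 4.35 in the control. For muscle markers, of 27 tested members 26 rose, 1 fell and 0 did not pass (26 and 1 adjusted over the list alone), median 0.94 (limma's camera adjusted p = 4.04e-08, and adjusted p = 0.277 with an estimated correlation), with the myosin gene unc-54 at 1.49 ± 0.11. For the moulting cycle, of 24 tested members 19 rose, 1 fell and 4 did not pass (19 and 1 adjusted over the list alone), median 2.01 (limma's camera adjusted p = 8.89e-07, and adjusted p = 0.201 with an estimated correlation), with noah-1 at 3.12 ± 0.11. For neuron markers, of 26 tested members 21 rose, 0 fell and 5 did not pass (21 and 0 adjusted over the list alone), median 1.14 (limma's camera adjusted p = 2.77e-05, and adjusted p = 0.201 with an estimated correlation).

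In the cell cycle and DNA replication list, of 35 tested members 0 rose, 35 fell and 0 did not pass (0 and 35 adjusted over the list alone), median -0.82 (limma's camera adjusted p = 3.62e-13, and adjusted p = 0.277 with an estimated correlation). In the oogenesis and eggshell list, of 32 tested members 0 rose, 29 fell and 3 did not pass (0 and 29 adjusted over the list alone), median -0.82 (limma's camera adjusted p = 8.87e-10, and adjusted p = 0.291 with an estimated correlation), with pos-1 at -1.32 ± 0.08 and egg-3 at -1.21 ± 0.08. Antimicrobial peptide genes were higher: of 36 tested members 29 rose, 0 fell and 7 did not pass (29 and 1 adjusted over the list alone), median 1.03 (limma's camera adjusted p = 1.40e-04, and adjusted p = 0.291 with an estimated correlation), with nlp-24 at 1.38 ± 0.13 and nlp-30 at 1.44 ± 0.16. The list of CUB-domain and dod genes held dod-24, an infection-response gene, with a log2 fold change of 2.56 ± 0.09 (SE). In that list of 17 tested members 12 rose, 2 fell and 3 did not pass (13 and 2 adjusted over the list alone), median 0.71 (limma's camera adjusted p = 0.0242, and adjusted p = 0.291 with an estimated correlation). C-type lectins, PMK-1 dependent genes and lysozymes did not pass as lists. For C-type lectins 48 rose and 13 fell of 98 (limma's camera adjusted p = 0.0643), and for PMK-1 dependent genes 8 rose and 3 fell of 17 (limma's camera adjusted p = 0.177). For lysozymes, 2 rose and 1 fell of 9 (limma's camera adjusted p = 0.870). The ribosomal RNA row rrn-1.1 was at 5463 ± 3309 CPM in the control and 489.5 ± 241 CPM on E. faecalis. Such rows varied widely within the control, from 1.28% to 11.3% of a library's counts. The library kit of each sample is not known, so a difference in library preparation cannot be told apart from the treatment here.

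Among the genes with the largest fold changes, pqn-2 had no count in the OP50 control and was at least 88.5-fold higher on E. faecalis, with the floor at 3 counts over the group. abu-8, of a family of glutamine- and asparagine-rich proteins, was 238 times as high with a counting interval of 65.6 to 1976; similar family members can share its reads. Lower genes were fat-5 (-3.81 ± 0.34) and fat-7 (-2.37 ± 0.08), both desaturase genes, the aspartyl protease gene asp-12 (-3.23 ± 0.23), the early embryonic transcript vet-2 (-2.70 ± 0.25), the cytochrome P450 genes cyp-13A12 (-2.46 ± 0.27) and cyp-35C1 (-2.41 ± 0.27), and the caveolin gene cav-1 (-2.35 ± 0.18), as log2 fold changes with SE. In all, 10078 genes changed (edgeR, adjusted p below 0.05): 5452 rose and 4626 fell, of which 3406 rose and 970 fell by at least 1 on the log2 scale. Among the called genes 54.1% rose with TMM scaling and 67.8% with upper-quartile scaling, and the median log2 fold change of all tested genes was 0.15 and 0.42 respectively.

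**Figure D2:**
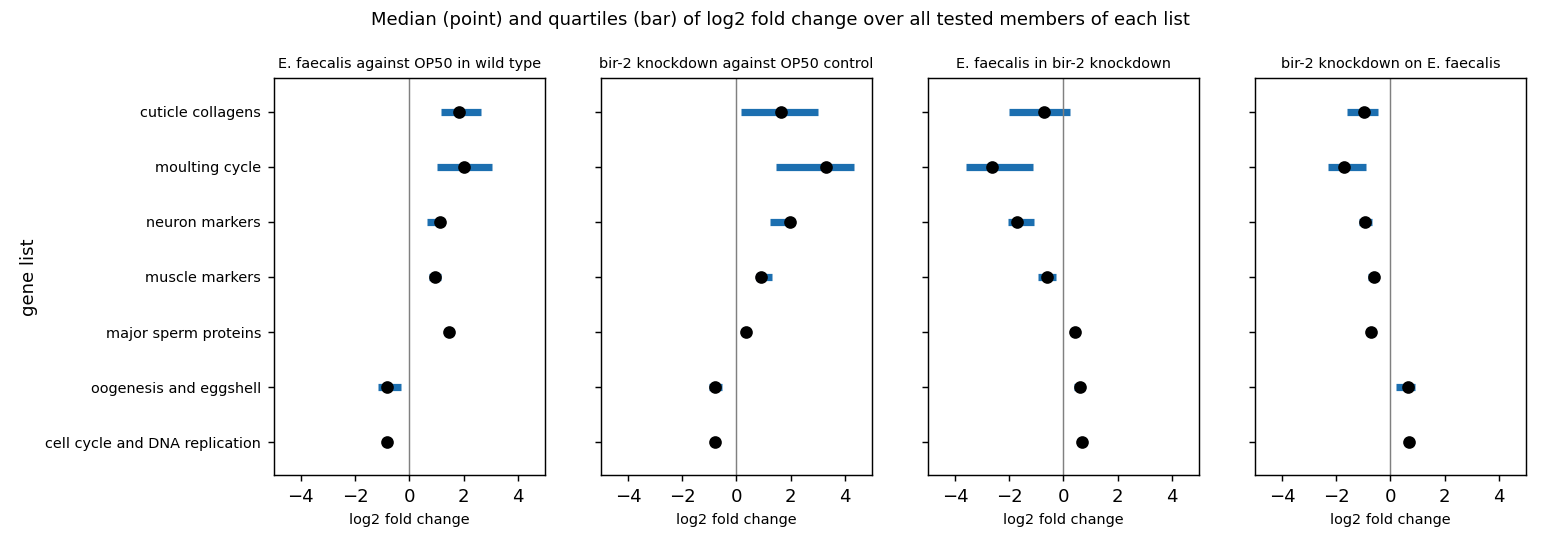
Median (points) and quartiles (bars) of the log2 fold change (horizontal axis) over all tested members of 7 gene lists (vertical axis), in the 4 pairwise comparisons. The cell cycle list has a median of -0.82 for the group labelled wild type on E. faecalis and -0.80 for the bir-2 RNAi group, each against the OP50 control, and lies above 0 in the other 2 comparisons, where bir-2 itself goes against the label.

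The libraries labelled knockdown plus E. faecalis were set against the bir-2 RNAi group to ask what E. faecalis changed after the knockdown food. bir-2 was higher in them, against their label, so every direction here is between libraries as labelled. Genes higher in them included members of the propionate shunt, which breaks down propionate where vitamin B12 is low: acdh-1 (chromosome I, 6497436 to 6499560), an acyl-CoA dehydrogenase gene, rose from 0.154 ± 0.129 to 239 ± 2.41 CPM and hphd-1 from 36.4 ± 3.88 to 209 ± 10.6 CPM (SD, n = 4 each). In the OP50 control these were 1.69 ± 0.442 and 39.8 ± 6.85 CPM. In the propionate shunt and vitamin B12 list as a whole, of 25 tested members 13 rose, 9 fell and 3 did not pass (13 and 9 adjusted over the list alone), with limma's camera adjusted p = 0.352. The arginine kinase gene argk-1 had a log2 fold change of 5.38 ± 0.27, fat-5 of 5.12 ± 0.25, the cystathionine-lyase gene cth-1 of 2.75 ± 0.13, the folate transporter gene folt-2 of 2.56 ± 0.08 and col-95 of 3.12 ± 0.11 (SE). In the cell cycle and DNA replication list, of 35 tested members 35 rose, 0 fell and 0 did not pass (35 and 0 adjusted over the list alone), median 0.67 (limma's camera adjusted p = 3.72e-11, and adjusted p = 0.190 with an estimated correlation). In the oogenesis and eggshell list, of 32 tested members 30 rose, 0 fell and 2 did not pass (30 and 0 adjusted over the list alone), median 0.62 (limma's camera adjusted p = 9.67e-09, and adjusted p = 0.413 with an estimated correlation).

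The moulting cycle was lower in the libraries labelled knockdown plus E. faecalis than in the bir-2 RNAi group: of 24 tested members 1 rose, 22 fell and 1 did not pass (1 and 22 adjusted over the list alone), median -2.62 (limma's camera adjusted p = 1.59e-10, and adjusted p = 0.0192 with an estimated correlation), with noah-1 at -3.95 ± 0.11. Among neuron markers, of 26 tested members 0 rose, 24 fell and 2 did not pass (0 and 24 adjusted over the list alone), median -1.70 (limma's camera adjusted p = 1.93e-10, and adjusted p = 0.0120 with an estimated correlation). For nuclear hormone receptors, 6 of 169 rose (6 adjusted over the list alone), 49 did not pass and the others fell, median -0.84 (limma's camera adjusted p = 4.98e-07, and adjusted p = 0.0104 with an estimated correlation). Immune signalling components were lower too: of 31 tested members 2 rose, 26 fell and 3 did not pass (2 and 26 adjusted over the list alone), median -0.85 (limma's camera adjusted p = 1.11e-05, and adjusted p = 0.0120 with an estimated correlation). That list was shifted higher in the bir-2 RNAi group against OP50: of 31 tested members 22 rose, 4 fell and 5 did not pass (22 and 4 adjusted over the list alone), median 0.90 (limma's camera adjusted p = 0.00136, and adjusted p = 0.0556 with an estimated correlation). In the group labelled wild type on E. faecalis against OP50, of 31 tested members 19 rose, 6 fell and 6 did not pass (19 and 6 adjusted over the list alone), median 0.49 (limma's camera adjusted p = 0.114). Between the libraries labelled knockdown plus E. faecalis and the bir-2 RNAi group, zip-2, a bZIP transcription factor gene of infection responses, had a log2 fold change of -1.64 ± 0.08, and tir-1, an adaptor gene upstream of the p38 kinase, of -1.66 ± 0.11 (SE). In the fasting and lipid breakdown list, in the same comparison, of 25 tested members 4 rose, 16 fell and 5 did not pass (4 and 16 adjusted over the list alone), median -1.05 (limma's camera adjusted p = 0.00467, and adjusted p = 0.403 with an estimated correlation), with acs-2, an acyl-CoA synthetase gene, at -2.53 ± 0.10 and cpt-4 at -5.73 ± 0.34. Single genes with large falls were col-41 (-6.74 ± 0.16), lips-6 (-6.53 ± 0.24), cyp-35B1 (-5.74 ± 0.32), col-54 (-5.63 ± 0.22), dpy-1 (-5.29 ± 0.27) and nhr-113 (-4.86 ± 0.40). In all, 9281 genes changed (edgeR, adjusted p below 0.05): 4466 rose and 4815 fell, of which 460 rose and 2853 fell by at least 1 on the log2 scale. Among the called genes 48.1% rose with TMM scaling and 37.5% with upper-quartile scaling, and the median log2 fold change of all tested genes was 0.01 and -0.14 respectively.

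The libraries labelled knockdown plus E. faecalis were also set against the group labelled wild type on E. faecalis, to ask what the knockdown changed on the pathogen. The parents' food differed as well as the knockdown, and bir-2 was higher, not lower, in the libraries labelled as knockdown. acdh-1 was at 239 ± 2.41 CPM against 0.344 ± 0.242, hphd-1 at 209 ± 10.6 against 36.3 ± 1.19, and fat-5 at 32.3 ± 3.93 against 0.509 ± 0.401 CPM (SD, n = 4 each). argk-1 had a log2 fold change of 6.44 ± 0.32, cth-1 of 2.89 ± 0.14 (SE), and folt-2 was at 187 against 35.4 CPM. Sperm, collagen and muscle genes were lower: for major sperm proteins of 34 tested members 0 rose, 33 fell and 1 did not pass (0 and 33 adjusted over the list alone), median -0.71 (limma's camera adjusted p = 1.77e-08, and adjusted p = 0.368 with an estimated correlation). For cuticle collagens, of 141 tested members 6 rose, 109 fell and 26 did not pass (7 and 111 adjusted over the list alone), median -0.96 (limma's camera adjusted p = 4.22e-14, and adjusted p = 0.368 with an estimated correlation). For muscle markers, of 27 tested members 0 rose, 23 fell and 4 did not pass (0 and 23 adjusted over the list alone), median -0.60 (limma's camera adjusted p = 9.76e-06, and adjusted p = 0.286 with an estimated correlation). In the cell cycle and DNA replication list, of 35 tested members 34 rose, 0 fell and 1 did not pass (34 and 0 adjusted over the list alone), median 0.70 (limma's camera adjusted p = 9.33e-14, and adjusted p = 0.211 with an estimated correlation).

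These defence lists were shifted lower in the libraries labelled knockdown plus E. faecalis than in the group labelled wild type on E. faecalis. For C-type lectins, of 98 tested members 10 rose, 48 fell and 40 did not pass (10 and 47 adjusted over the list alone), median -0.51 (limma's camera adjusted p = 0.0213, and adjusted p = 0.241 with an estimated correlation), with clec-4 at -1.75 ± 0.14 and clec-88, in the other direction, at 1.29 ± 0.09. For PMK-1 dependent infection genes, of 17 tested members 4 rose, 11 fell and 2 did not pass (4 and 11 adjusted over the list alone), median -0.77 (limma's camera adjusted p = 0.0253, and adjusted p = 0.241 with an estimated correlation), with irg-4 at -1.35 ± 0.12 and T24B8.5 at -1.31 ± 0.12. For antimicrobial peptides, of 36 tested members 2 rose, 23 fell and 11 did not pass (2 and 23 adjusted over the list alone), median -0.66 (limma's camera adjusted p = 0.00117, and adjusted p = 0.368 with an estimated correlation). In the programmed cell death list, of 27 tested members 16 rose, 4 fell and 7 did not pass (17 and 4 adjusted over the list alone), median 0.40 (limma's camera adjusted p = 0.00979, and adjusted p = 0.211 with an estimated correlation), with ced-9 at 0.86 ± 0.09. Single genes lower were col-41 (-5.59 ± 0.16), lips-6 (-5.25 ± 0.25), cpt-4 (-4.88 ± 0.36) and cyp-33A1 (-3.48 ± 0.10). The mitochondrially encoded cytochrome b gene ctb-1 was at 0.0871 ± 0.0152 CPM against 683 ± 85.8, and was also near 0 in 1 library of the OP50 control and 2 of the bir-2 RNAi group; its call was lost under limma-voom with and without sample weights. In all, 9335 genes changed (edgeR, adjusted p below 0.05): 4279 rose and 5056 fell, of which 512 rose and 2138 fell by at least 1 on the log2 scale. Among the called genes 45.8% rose with TMM scaling and 31.2% with upper-quartile scaling, and the median log2 fold change of all tested genes was -0.16 and -0.39 respectively.

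**Figure D3:**
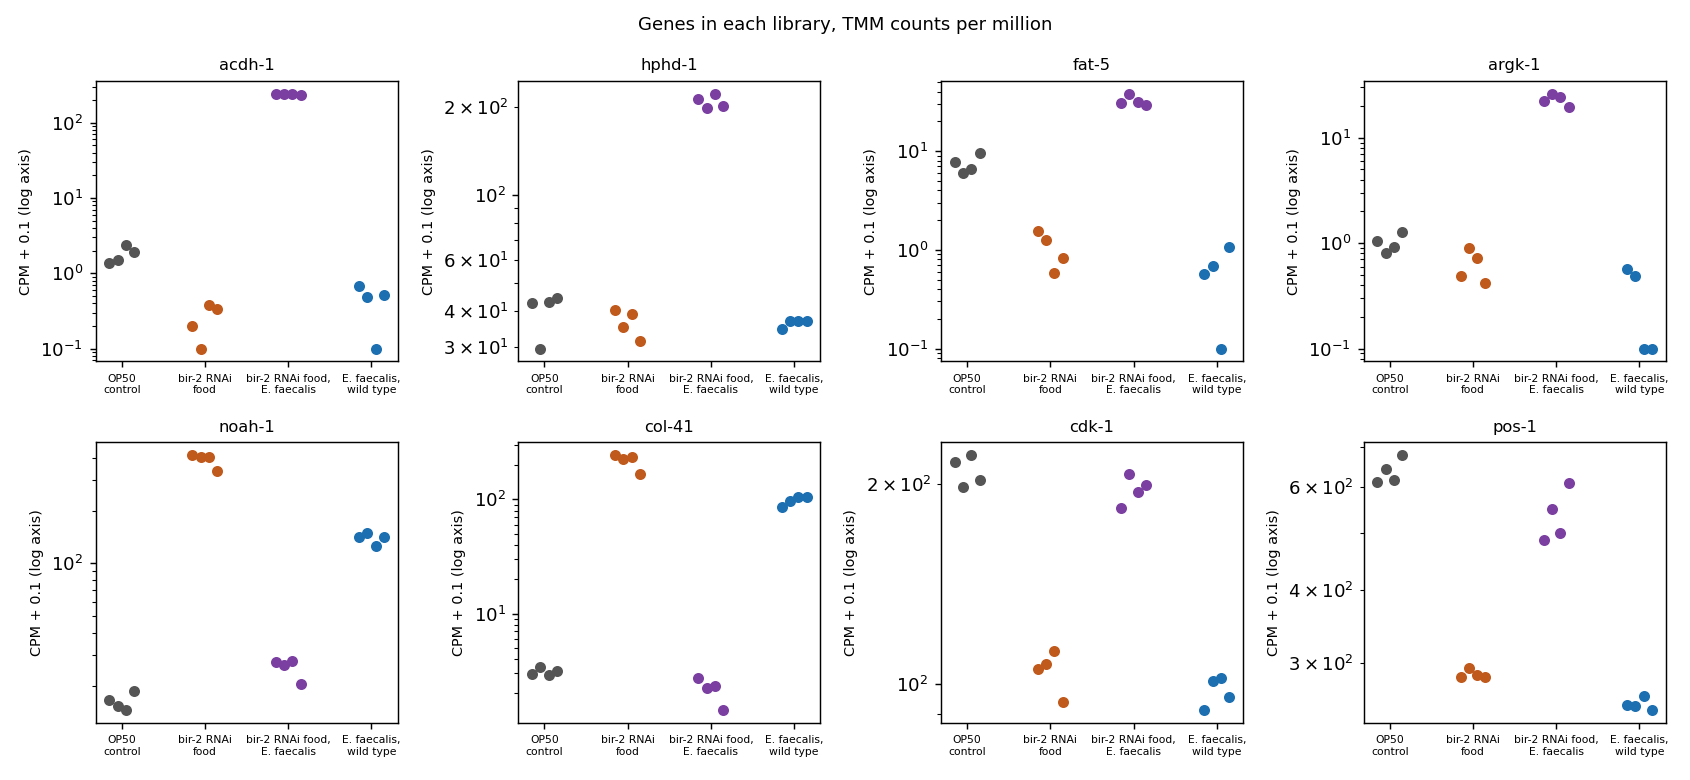
TMM-scaled CPM, with a small constant added, on a log axis for 8 genes in each library (points) of the 4 labelled groups. acdh-1 averages 239 CPM in the libraries labelled knockdown plus E. faecalis and 1.69 or less in the other groups, while noah-1 averages 391 CPM in the bir-2 RNAi group and 139 in the group labelled wild type on E. faecalis.

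The interaction asked whether the effect of E. faecalis differed between the arms with and without the knockdown food. bir-2 was high in the libraries labelled knockdown plus E. faecalis and low in those labelled wild type on E. faecalis. In the arm labelled wild type the parents' food changed too, from OP50 to E. faecalis. In the other arm only the animals' own food changed, from the RNAi food. The term therefore does not separate the knockdown from the foods. If the labels on E. faecalis were exchanged, the term would be minus the sum of both knockdown effects and no interaction. The interaction was past the threshold for 11130 genes (edgeR, adjusted p below 0.05), 4856 positive and 6274 negative. Of these, 3057 positive and 5214 negative terms were at least 1 in size on the log2 scale. acdh-1 had an interaction of 12.56 ± 0.48, fat-5 of 8.93 ± 0.41, argk-1 of 7.15 ± 0.58, lips-6 of -12.94 ± 0.38 and col-41 of -11.77 ± 0.22 on the log2 scale (SE). The lowest groups of acdh-1, fat-5, argk-1 and lips-6 held 8, 18, 9 and 15 counts over 4 libraries, so the sizes of these terms rest on few counts. In the cell cycle and DNA replication list, of 35 tested members 35 were positive, 0 were negative and 0 did not pass (35 and 0 adjusted over the list alone), and in the moulting cycle list 1 was positive and 23 negative of 24 (limma's camera adjusted p = 8.04e-13 and 6.99e-08, and adjusted p = 0.197 and 0.0813 with an estimated correlation). Among the called genes 43.6% were positive with TMM scaling and 32.9% with upper-quartile scaling, and the median log2 fold change of all tested genes was -0.39 and -0.83 respectively.

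The effects of E. faecalis in the 2 arms, which share no library, had opposite signs for most genes called in both. bir-2 was high in the group on E. faecalis labelled knockdown and low in the one labelled wild type. The arms also differ in the food set against E. faecalis, and the parents' food changed only in the arm labelled wild type. Across genes, which are not independent replicates, the log2 fold changes of the arms had Pearson r = -0.570. Of 7442 genes called in both, 3394 rose in the arm labelled wild type and fell in the arm labelled knockdown, where independent lists would give 1893, and 3552 did the reverse against 1490. 379 rose in both against 1756, and 117 fell in both against 1606. The knockdown effects without and with E. faecalis, again without a shared library, had r = -0.763. Of the 8080 genes called in both, 98.6% went opposite ways. col-41, for example, had 6.18 without and -5.59 with E. faecalis. With E. faecalis, bir-2 was higher, not lower, in the libraries labelled knockdown. The contrasts are also unlike in food. Without E. faecalis the animals and their parents ate different foods, and with it only the parents did. With the labels of the groups on E. faecalis exchanged, r would be 0.763 and 98.6% would go the same way. The bir-2 RNAi group and the group labelled wild type on E. faecalis, each against the same OP50 control, gave r = 0.840, with 4436 genes higher in both and 4045 lower in both, where independent lists would give 2194 and 1514. Simulated unchanged groups sharing simulated controls, all drawn at each gene's mean over the libraries, gave r = 0.502 and 0 shared calls on average over 20 simulations. With the real controls split into pairs, r averaged 0.725 over 6 splits, with 3714 genes higher in both and 3596 lower in both on average. The covariance was 1.32, against 0.0384 in the simulations, a difference of 1.28.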

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

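Tests of what bir-2 follows, of RNAi food reads, of exchanged labels, of library totals, of germline share, of stages and of the mitochondrial values were chosen only after those results were seen; the counts over other splits were planned, and setting apart the splits with 2 libraries of each group on each side was not. bir-2 was lower in the bir-2 RNAi group and in the group labelled wild type on E. faecalis than in the OP50 control, and not in the libraries labelled knockdown plus E. faecalis. Reads from the RNAi food would raise bir-2 in the animals that ate it, whereas it had a log2 fold change of -0.79 there and was lower in all 4 libraries. Relative to the mean of 67 oogenesis and cell cycle genes it differed from the control by -0.0168 in the bir-2 RNAi group (two-sided exact permutation p = 0.83), by -0.17 in the group labelled wild type on E. faecalis (exact permutation p = 0.200) and by 0.30 in the libraries labelled knockdown plus E. faecalis (exact permutation p = 0.0571), so the lower level may follow those lists and does not by itself show a knockdown. An exchange of the labels of the groups on E. faecalis needs bir-2 higher in the libraries labelled knockdown plus E. faecalis. It was, by 1.11 on the log2 scale, but that difference raised the question and so cannot test it. The mean of the 67 genes differed from the control by -0.77 in the group labelled wild type on E. faecalis. In the libraries labelled knockdown plus E. faecalis it differed by -0.13, so part of the 1.11 may follow those lists. The exchange stays open as a hypothesis beside a knockdown lost after the move to E. faecalis and the parents' food, both untested. A lost knockdown would not account for the low bir-2 in the group labelled wild type on E. faecalis, 18.3 CPM against 35.3 in the control. An exchange would also turn the knockdown effects with and without E. faecalis from r = -0.763 and 98.6% opposite to r = 0.763 and 98.6% in the same direction, and would place the groups on principal component 1 by knockdown label, but nothing here shows that the knockdown acts alike on both foods, so these values do not decide it.

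Oogenesis and cell cycle lists were lower, and moulting, neuron and muscle lists higher, in the bir-2 RNAi group and in the group labelled wild type on E. faecalis than in the OP50 control by limma's camera; with an estimated correlation only the moulting and neuron lists in the bir-2 RNAi group passed, and the other calls had an adjusted p of 0.191 to 0.291. The medians of the moulting and oogenesis lists in the group labelled wild type on E. faecalis differed by 2.83 on the log2 scale. Thinned to equal library totals, they differed by 2.88. Fold changes are already scaled to library totals and thinning keeps proportions, so this test could hardly show an effect of different totals. A lower germline share alone would raise somatic lists alike, but the moulting median exceeded the muscle median by 2.39 in the bir-2 RNAi group (bootstrap interval over genes 0.94 to 3.19). That interval treats the genes as independent and does not cover the spread between libraries. Sperm lists, also germline, were shifted higher by camera in the group labelled wild type on E. faecalis, though not with an estimated correlation. Another mix of stages may contribute and cannot be told apart from the treatment for these samples: vitellogenins, made by adults, had a median of 0.10 in the group labelled wild type on E. faecalis, with 3 of 6 below 0, and of -0.35 in the bir-2 RNAi group, with 6 of 6 below 0. Effects of bir-2, of E. faecalis and of the foods on growth remain open and untested.

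Some mitochondrially encoded genes, 5 in number, read near 0 in some libraries, with such a gene in all 16 libraries, and at 11.6% to 229.6% of their median level in the others. Loss of mitochondrial RNA would lower the other mitochondrial genes in the same libraries, but where such a gene was near 0 the median level of 7 other mitochondrial protein genes was at least 95.9% of that where it was present. All-or-none estimates of the quantification step are a candidate explanation that the values leave undecided: 34 values lay near 0 and 0 between 1% and 10% of the gene's level, but ctc-1 was at 217 CPM (11.6%) in replicate 4 of the libraries labelled knockdown plus E. faecalis and nduo-2 at 46.2 CPM (44.6%) in replicate 2 of the OP50 control, neither near 0 nor near the median. nduo-2 was near 0 in 12 libraries, ctc-2 in 9, ctb-1 in 7, nduo-6 in 4 and ctc-1 in 2. No further explanation was tested.

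Single libraries stood apart in 25 of 225 groups of 4 values tested, where chance gives about 11.2: the gap to the nearest other library was a larger share of the group's range than Dixon's 95% critical value. In 6 of them a library with 2 to 3 counts stood against 0 in the others, where counting alone sets that share, and the other 19 compare with about 10.9 by chance in 219 groups. In the OP50 control, a library lay apart for abu-8 in replicate 4 at 0.263 CPM, against 0 in the others, for abu-7 in replicate 4 at 0.263 CPM, against 0 in the others, for abu-15 in replicate 3 at 0.180 CPM, against 0 in the others. In the same group, a library lay apart for bah-1 in replicate 2 at 1.22 CPM, against 0.343 to 0.450 in the others, for oac-1 in replicate 1 at 0.257 CPM, against 0 in the others, for tba-8 in replicate 2 at 0.262 CPM, against 0 in the others. In the same group, a library lay apart for hphd-1 in replicate 2 at 29.6 CPM, against 42.6 to 44.2 in the others, for bus-1 in replicate 2 at 1.31 CPM, against 0.343 to 0.450 in the others. In the bir-2 RNAi group, a library lay apart for abu-7 in replicate 4 at 3.44 CPM, against 1.24 to 1.46 in the others, for lips-6 in replicate 4 at 61 CPM, against 79.4 to 82.8 in the others, for lron-2 in replicate 1 at 4.69 CPM, against 6.89 to 7.28 in the others. In the same group, a library lay apart for bah-1 in replicate 4 at 22.3 CPM, against 26.8 to 27.2 in the others, for vet-2 in replicate 4 at 6.0 CPM, against 4.31 to 4.45 in the others, for oac-1 in replicate 4 at 9.60 CPM, against 12.7 to 13.2 in the others. In the libraries labelled knockdown plus E. faecalis, a library lay apart for nhr-73 in replicate 4 at 0 CPM, against 0.504 to 0.534 in the others, for hrg-7 in replicate 1 at 241 CPM, against 253 to 256 in the others, for cth-1 in replicate 3 at 78.8 CPM, against 57.3 to 59.8 in the others. In the same group, a library lay apart for col-126 in replicate 4 at 6.43 CPM, against 9.30 to 9.82 in the others, for pho-10 in replicate 1 at 0.168 CPM, against 0 in the others. In the group labelled wild type on E. faecalis, a library lay apart for bir-2 in replicate 4 at 15.3 CPM, against 18.8 to 19.5 in the others, for abu-7 in replicate 4 at 6.13 CPM, against 7.25 to 7.48 in the others, for rrn-3.56 in replicate 4 at 781 CPM, against 367 to 419 in the others. In the same group, a library lay apart for oac-1 in replicate 2 at 5.76 CPM, against 4.26 to 4.46 in the others, for hphd-1 in replicate 1 at 34.5 CPM, against 36.9 in the others, for cpt-4 in replicate 2 at 29.7 CPM, against 26.5 to 26.9 in the others. Replicate 4 of the bir-2 RNAi group held 5 of them.

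As labelled, the effect of E. faecalis differed between the arms, by the edgeR interaction term, for 11130 genes. In that term 19 lists were shifted by camera, or 0 of 47 with an estimated correlation and 38 by fry. Of 52 genes named in a pairwise comparison 50 had an interaction; nspe-7 (0.17, edgeR adjusted p = 0.793) and col-126 (-0.42, edgeR adjusted p = 0.189) did not pass. On the log2 scale the interaction was 1.90 for bir-2, 12.56 for acdh-1, 8.93 for fat-5, 7.15 for argk-1, 5.18 for col-95 and 4.46 for rrn-1.2. It was -14.45 for tba-8, -13.83 for mltn-5, -12.94 for lips-6, -11.77 for col-41 and -11.70 for ctb-1. Groups at or near 0 counts make the fitted values of tba-8, mltn-5 and ctb-1 depend on the prior count, so these are no measured folds, and the interaction of ctb-1 was lost under limma-voom with and without sample weights. The values of acdh-1, fat-5, argk-1 and lips-6 rest on few counts, with 8, 18, 9 and 15 over the 4 libraries of their lowest groups. The ribosomal RNA row rrn-1.2 varied widely within groups, for example 4376 ± 2649 CPM in the bir-2 RNAi group (SD, n = 4). bir-2 was high in the group labelled knockdown plus E. faecalis and low in the one labelled wild type on E. faecalis, and both enter every value. With those labels exchanged, each value would be minus the sum of both knockdown effects and no interaction. The foods of the arms differ as well and are not separated from the knockdown.

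Other splits of the same libraries were refitted on the libraries compared. For E. faecalis in the arm labelled wild type, the real split called 9649 genes and the highest of the others 1, so 1 of 35 splits gave as many. For the bir-2 RNAi group against OP50, the real split called 9820 genes and the highest of the others 0, so 1 of 35 splits gave as many. For E. faecalis after the knockdown food, the real split called 9110 genes and the highest of the others 1, so 1 of 35 splits gave as many. For knockdown on E. faecalis, the real split called 9203 genes and the highest of the others 1, so 1 of 35 splits gave as many. For the interaction, 1 of 100 splits gave 11130 genes, and the highest other gave 4. The real split thus called the most genes in each, and 1 of 35 is the smallest share that the pairwise splits can give. The other splits mix the labelled groups, so the group differences widen their fitted spread and hold their calls low. Separate cultures are not stated for the replicates, so chance differences between cultures are not excluded. For the number of shifted lists by camera, the splits do not settle whether chance is excluded. For E. faecalis in the arm labelled wild type, 6 of 35 splits shifted at least the 22 lists of the real split, the highest other being 25. For the bir-2 RNAi group against OP50, 6 of 35 splits shifted at least the 20 lists of the real split, the highest other being 21. For E. faecalis after the knockdown food, 8 of 35 splits shifted at least the 19 lists of the real split, the highest other being 20. For knockdown on E. faecalis, 2 of 35 splits shifted at least the 22 lists of the real split, the highest other being 22. For the interaction it was 21 of 100 splits, with 19 lists in the real one and 25 in the highest other. In the pairwise comparisons, every other split that shifted as many lists kept 3 of the 4 libraries of a labelled group together, and so held part of the real difference. The 18 splits with 2 libraries of each group on each side shifted at most 13, 15, 14 and 14 lists, in the same order, but are too few for a share under 0.05. For the interaction, 13 of the draws had 2 libraries of each group on each side, also too few, and shifted at most 13.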

How the results depend on the processing

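Leaving out ribosomal RNA rows, thinning and leaving out the farthest library of each group were chosen after seeing the data. Values below run in the order E. faecalis in the arm labelled wild type, knockdown against OP50, E. faecalis after the knockdown food, knockdown on E. faecalis, and interaction. Against a log2 fold change of 1 (glmTreat) the genes called were 2360, 2311, 1843, 609 and 6371; that test asks for a larger change. Lists shifted were 0, 3, 4, 0 and 0 with an estimated correlation in camera, and 35, 40, 35, 39 and 38 by fry, which does not compare a list with other genes. With DESeq2 fold changes the correlation was -0.453 between the E. faecalis effects and -0.598 between the knockdown effects. It was 0.773 for the effects sharing the OP50 control. DESeq2 tested 16783 to 17199 genes per pairwise comparison, more than the main fit, so the genes differed as well as the method. The cause of the differences from the main correlations was not tested. Leaving out a library gave -0.569 to -0.530, -0.752 to -0.723 and 0.820 to 0.847. It gave 9719 to 10228, 9763 to 10336, 8880 to 9450, 8717 to 9483 and 10994 to 11300 genes. The log2 fold change of bir-2 was -0.83 to -0.71 against OP50 and 1.04 to 1.16 on E. faecalis with a library left out, and -0.59 and 0.88 with upper-quartile factors. Of 2578 alternative values for 90 named-gene results, 2574 kept direction and side of the threshold, 4 lost the threshold (ctb-1 under limma-voom, with and without weights) and 0 reversed. These genes were chosen for large fold changes past the threshold, so most were likely to keep both, and the count says little about other genes. The stricter thresholds were not applied to them. Summing rows with the same symbol was not run, as none shared one.

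The replicate numbers did not pair the libraries: of 24 same-numbered pairs 0 had deviations correlated above 0.1 (-0.18 to 0.08), and 3 of 16 libraries matched their own number best. With the replicate block, 10010, 10022, 9203, 9208 and 11067 genes were called.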

Other observations

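The tests reported here use lists and comparisons that were planned. The following lists are for the bir-2 RNAi group against the OP50 control. In the endoplasmic reticulum unfolded protein response list, of 29 tested members 21 rose, 4 fell and 4 did not pass (21 and 5 adjusted over the list alone), median 0.80 (limma's camera adjusted p = 0.00635, and adjusted p = 0.319 with an estimated correlation). Its members with the smallest adjusted p were abu-12 (4.06 ± 0.15), abu-13 (3.77 ± 0.16) and abu-14 (4.60 ± 0.28), of a family of glutamine- and asparagine-rich proteins whose members can share reads, and pdi-2 (1.47 ± 0.10), a protein disulfide isomerase gene, as log2 fold changes with SE. In the list of infection genes that depend on HLH-30, a transcription factor of autophagy genes, of 15 tested members 11 rose, 0 fell and 4 did not pass (11 and 0 adjusted over the list alone), median 1.19 (limma's camera adjusted p = 0.0188, and adjusted p = 0.191 with an estimated correlation), with sqst-1 at 1.42 ± 0.08 and clec-60 at 2.83 ± 0.22. In the glutathione S-transferases, of 35 tested members 19 rose, 2 fell and 14 did not pass (19 and 2 adjusted over the list alone), median 0.58 (limma's camera adjusted p = 0.0362, and adjusted p = 0.504 with an estimated correlation), with gst-4 at 2.07 ± 0.18. In the pharynx markers, of 14 tested members 11 rose, 1 fell and 2 did not pass (11 and 1 adjusted over the list alone), median 1.19 (limma's camera adjusted p = 0.0322, and adjusted p = 0.387 with an estimated correlation), with the myosin gene myo-2 at 2.05 ± 0.17 and pha-4, a transcription factor gene, at 2.43 ± 0.21. In the F-box and MATH-BATH genes, of 174 tested members 33 rose, 71 fell and 70 did not pass (30 and 70 adjusted over the list alone), median -0.16 (limma's camera adjusted p = 0.0272, and adjusted p = 0.504 with an estimated correlation). Upper-quartile scaling shifted the median of all tested genes, and with it this list's median to 0.05; relative to the median of all tested genes it was -0.34 with TMM and -0.34 with upper-quartile scaling.

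In the fatty acid synthesis and desaturation list, of 25 tested members 10 rose, 3 fell and 12 did not pass (9 and 3 adjusted over the list alone), median 0.12 (limma's camera adjusted p = 0.733), in the bir-2 RNAi group against the OP50 control, with fasn-1, the fatty acid synthase gene, at 1.18 ± 0.11 and fat-7 at -1.94 ± 0.07. In the libraries labelled knockdown plus E. faecalis against the group labelled wild type on E. faecalis, where bir-2 goes against the label, of 25 tested members 6 rose, 10 fell and 9 did not pass (6 and 10 adjusted over the list alone), median -0.06 (limma's camera adjusted p = 0.978). Vitellogenins, yolk protein genes of adults, did not pass as a list in the group labelled wild type on E. faecalis against OP50: of 6 tested members 2 rose, 0 fell and 4 did not pass (2 and 0 adjusted over the list alone) (limma's camera adjusted p = 0.668). In the bir-2 RNAi group against OP50, of 6 tested members 0 rose, 4 fell and 2 did not pass (0 and 5 adjusted over the list alone), with limma's camera adjusted p = 0.0594. The labels call the animals L4 larvae.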
